A study of Arabidopsis thaliana with 12 samples.

How the data were processed

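The samples were 12 oligonucleotide arrays of Arabidopsis thaliana inflorescences that carried flower buds of stages 1 to 9. The plants were of the Landsberg erecta background and expressed HANABA TARANU (HAN), a GATA-type transcription factor of flower development, from the 35S promoter as a fusion to the glucocorticoid receptor (35S:HAN-GR). In such a fusion the hormone-binding part of the receptor holds the protein in the cytoplasm until dexamethasone (Dex) lets it enter the nucleus. Plants were treated with 10 µM Dex or with a mock solution, and tissue was taken 4, 12 and 72 h later. Each array co-hybridised RNA of Dex-treated and mock-treated plants of one time point, 4 arrays per time point, and the labels call the 4 arrays of a time point biological replicates. Per the labels, Dex RNA carried Cy5 on 2 arrays of each time point and Cy3 on the other 2. A sample taken at 0 h is not analysed here.

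The values deposited by the authors are log2 ratios of the channels of one array. Per the labels' protocols, total RNA was amplified by in vitro transcription and the dyes were coupled to the amplified RNA. The background correction, the normalization, the centring and the direction of the ratio are not given in the sources used here. The base of the log was read from the values, whose largest and smallest entries, 6.64 and -6.64, are log2 of 100 and of 0.01. The column medians over all rows were -0.06, 0.07, 0.10 and -0.10 for 4 h replicates 1 to 4, -0.09, 0.12, 0.12 and -0.10 for 12 h, and 0.13, -0.15, -0.28 and 0.10 for 72 h. The table held 26540 rows, of which 450 controls and blanks were left out and 26090 were gene probes. Between 3705 and 4202 gene probes per array had no value, and 9.43% to 17.2% of the values of an array sat exactly at a limit, nearly all with one sign on a given array. A value at a limit is a bound and was treated as missing. No column of the table was without a sample (0 unmapped). Signal over background cannot be judged from ratios, so only the number of arrays limits the precision that can be stated.

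The direction of the ratio was examined on the genes. With values at the limits set missing, arrays of opposite labelled dye at one time point correlated above 0 across tested genes, at 0.20 to 0.64 at 4 h, 0.39 to 0.49 at 12 h and 0.06 to 0.41 at 72 h. By the rule set beforehand the values were then used as deposited, since the ratios run with the treatment and not with the dye. With the limit values kept, arrays whose blank spots had opposite signs correlated at -0.82 to -0.80 at 4 h, -0.72 to -0.67 at 12 h and -0.75 to -0.49 at 72 h. At 4 h this includes pairs with the same labelled dye, so over all probes the labels alone do not settle the direction. Dex over mock is the likely direction, because the ratios follow the treatment and the mock RNA is labelled as the control. It is stated nowhere in the sources used here, and with the sign turned every rise below becomes a fall and every fall a rise.

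Probes were named through the platform annotation, whose gene IDs were updated with the TAIR10.1 gene table. Of the gene probes, 13960 had 1 gene name, 0 had several and 12130 had none and are unnamed here. The IDs of 13912 matched, giving 13698 loci, and 1496 of these had a symbol beyond the locus identifier. Probes of one locus were averaged. The deposited rows were identical in all 206 loci with 2 probes that were matched by gene ID, and differed for AT5G22700, whose 2 probes share a locus name but not a gene ID. A gene, or an unnamed probe, was tested when it had a value on at least 3 of the 4 arrays at each time point. This left 18125 features, 10654 of them named, and 211 tested features held exactly the values of another one.

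Each array was centred on its median over the tested features. A linear model with a mean per time point and a term for the labelled dye was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation, so that the time points shared one estimate of the spread. Contrasts of features with missing values were computed from the covariance of their own pattern of values. P-values were two-sided and adjusted with the Benjamini-Hochberg method over all features, with a threshold of 0.05. Values in the text are means of the centred log2 ratios with the SD over arrays, adjusted p-values are those of limma, and a difference between time points has the standard error (SE) of the fit. The tests, the 19 gene lists with their 276 loci, the rule for the genes named and most of the other settings tried were chosen before the data were examined. Lists with at least 3 measured members were tested with limma's cameraPR on the moderated statistics with a preset correlation of 0.01, in place of camera, which accepts no missing values. The estimated correlation and fry were run on genes with all 12 values. Overlaps were tested with Fisher's exact test, two-sided.

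The rule for the genes named takes the 12 largest rises and the 12 largest falls of each time point. These are among named genes past the threshold with the same sign on all 4 arrays. Also taken are up to 4 members per list past the threshold, those with the smallest adjusted p. Between time points it takes the 5 largest differences of each direction among named genes past the threshold. The first 6 rises and 6 falls of each time point are given, in that order.

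The fit was tested on simulated arrays with the real pattern of missing values and 18125 features, 200 of them changed at 12 h only. It recovered 12 of 50 features changed by 0.5 on the log2 scale, 41 of 50 changed by 1, 47 of 50 changed by 2 and 49 of 50 changed by 3, with 0 calls among unchanged features at 12 h. For the simulated differences between time points, 9 unchanged features were called between 72 and 12 h, 1 between 12 and 4 h and 0 between 72 and 4 h. Of random lists of 5 genes, 4.50% had a list p under 0.05. The simulated features varied independently of each other. The share of random lists therefore does not test lists whose members move together. No dye effect was simulated, and the spread came from a fit whose dye was read from the signs of the blank spots. The main fit used the labelled dye instead. Recovery and false calls under the spread of the main fit were thus not simulated. The alternatives were other centring, scaling and weighting, other dye and replicate terms, other filters and thresholds, each array left out in turn, and other list tests. Those chosen after seeing the data were the dye read from the blank spots, limit values kept, identical rows kept once, symbol families and a glutaredoxin list.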

Results

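The response to Dex of inflorescences that carry HAN-GR was measured at 4, 12 and 72 h. Each of the 4 arrays per time point set Dex against mock RNA of the same time. No Dex-treated plants without the fusion were among the samples. Effects of Dex itself therefore cannot be told apart from those of HAN-GR entering the nucleus. The series title speaks of HAN as a repressor that acts through several hormones, floral organ specification and the GATA3 family, which is the question the comparisons address. Signs below read as Dex over mock, the likely but unstated direction, and turning the sign would exchange all rises and falls. The list of 11 GATA factors, HAN among them, had no named probe among those used here, so the induced gene itself is not analysed here. Between 21888 and 22385 gene probes per array had a value.

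At 4 h, among named genes past the threshold with the same sign on all 4 arrays, AT5G50130 fell most, at -3.27 ± 0.11 (SD, n = 4, 9.64-fold). The chitinase family gene AT2G43620, at -3.14 ± 0.21, and AT3G11680, of the aluminium-activated malate transporter family, at -2.98 ± 0.13, were next. The glutaredoxin gene AT4G15680 (-2.63 ± 0.37), the bHLH gene AT1G61660 (-2.63 ± 0.28) and the cytochrome P450 gene CYP71B23 (-2.55 ± 0.59) followed. The largest rises were in AT1G70390, at 2.51 ± 0.30 (5.68-fold), the cold-regulated gene COR15B, at 2.32 ± 0.24, and CYP71B24, at 2.22 ± 0.26. AT3G14060 (2.14 ± 0.51), the AP2/ERF gene AT1G33760 (4.29-fold; log2 SD 0.22) and the nitrate transporter gene NRT2.5 (2.03 ± 0.51) were next. Each of these 12 genes moved the same way on 4 of 4 arrays, with limma adjusted p between 1.1e-06 for AT3G11680 and 0.023 for NRT2.5. NRT2.5 did not pass without 4 h replicates 1, 2 or 4 (adjusted p = 0.087, 0.082 and 0.11), nor with a replicate block (0.066) or limit values kept (0.56). Lower still, but measured on 3 arrays, were the glutaredoxin gene AT2G30540 (-4.79 ± 0.27; adjusted p = 2.3e-06) and scpl33 (-4.03 ± 2.31; adjusted p = 0.025), both named here after their values were seen.

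Among the hormone genes measured at 4 h, ARR15, a type-A response regulator induced by cytokinin, fell by 1.73 on the log2 scale (SD 0.41, n = 4; 3.32-fold; limma adjusted p = 0.00014). The auxin-responsive IAA29 was at -1.51 ± 0.77 (adjusted p = 0.011) and the jasmonate methyltransferase gene JMT at -0.88 ± 0.09 (adjusted p = 0.0026), both lower on 4 of 4 arrays. Of the organ genes, the YABBY gene YAB3, which marks the abaxial side of organs, was at -0.61 ± 0.14 and the organ growth gene JAG at -0.82 ± 0.11 (adjusted p = 0.0093 and 0.011). RBE, a zinc-finger gene of petal development, rose by 0.69 ± 0.18 (adjusted p = 0.0035), and PTL, a trihelix gene of perianth growth, was at -0.46 ± 0.11 (adjusted p = 0.022). Without 4 h replicates 3 or 4, YAB3 (adjusted p = 0.054 and 0.058) and JAG (0.060 and 0.057) did not pass. IAA29 did not pass without replicates 2 or 3 (adjusted p = 0.061 and 0.057), and PTL did not pass without replicates 2, 3 or 4 (adjusted p = 0.077, 0.11 and 0.094). With the 4 h arrays fitted alone IAA29 (adjusted p = 0.086) and PTL (0.081) did not pass, nor did PTL with limit values kept (0.076).

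In all, 2009 of 18125 features changed at 4 h, 763 higher and 1246 lower. Of the lower ones 419 fell and of the higher ones 153 rose by over 1 on the log2 scale. The count was 1315 without 4 h replicate 2, 1145 when only the 4 h arrays were fitted, 4619 with array weights and 1200 at adjusted p under 0.01.

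At 12 h, among named genes past the threshold with the same sign on all 4 arrays, the peroxidase gene AT2G38380 rose most. It was at 3.85 ± 0.83 (SD, n = 4, 14.4-fold), followed by the beta-glucosidase gene BGLU47, at 3.33 ± 0.49. AT2G25450, a dioxygenase gene of glucosinolate metabolism, was at 2.90 ± 0.37, SAL2 at 2.69 ± 0.57, the AP2/ERF gene TINY at 2.41 ± 0.18 and COR15B at 2.23 ± 0.66. Under the same conditions the largest falls were in the glutaredoxin gene AT2G30540, at -3.67 ± 0.36 (12.7-fold), and in AOP3, at -3.17 ± 0.39. AOP3 is another dioxygenase gene of glucosinolate metabolism. The glutaredoxin gene AT3G62930 was at -3.12 ± 0.29. AT3G11680 was at -2.77 ± 0.09, BGLU44 at -2.75 ± 0.19 and AT5G59080 at -2.71 ± 0.27. The adjusted p of these 12 genes lay between 1.5e-06 for AT3G11680 and 0.00019 for COR15B, and each kept its sign on 4 of 4 arrays. SAL2 did not pass with limit values kept (adjusted p = 0.058).

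RBE was 2.32-fold higher at 12 h (1.21 ± 0.22, n = 4; limma adjusted p = 6.8e-05), while YAB3 (-1.05 ± 0.13; adjusted p = 0.00023) and JAG (-0.90 ± 0.17; adjusted p = 0.0048) were lower. ARR15 was again lower, at -1.64 ± 0.12 (adjusted p = 0.00013), and JMT was at -0.68 ± 0.46 (adjusted p = 0.0087). The chlorophyll-binding protein gene LHCB4.1 was at -1.10 ± 0.69 (adjusted p = 0.016) and AMS, a regulator of the tapetum, at -0.36 ± 0.05 (adjusted p = 0.018). LHCB4.1 did not pass without 12 h replicates 1, 2 or 4 (adjusted p = 0.068, 0.076 and 0.076) or with no dye term (0.050), nor AMS without replicates 1, 2 or 3 (0.054, 0.089 and 0.12). Features that changed at 12 h numbered 2867, 967 higher and 1900 lower. Without 12 h replicates 2, 3 or 4 the count was 1833, 1780 or 1753, and with only the 12 h arrays fitted it was 4801. It was 6851 with array weights, 1671 at adjusted p under 0.01 and 1854 with a limit of 1.5-fold added. The median SD between the arrays of a time point was 0.19 at 12 h, 0.21 at 4 h and 0.34 at 72 h.

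At 72 h, among named genes past the threshold with the same sign on all 4 arrays, AT2G38380 again rose most, at 3.90 ± 0.88 (SD, n = 4, 14.9-fold). AT3G09950 (3.09 ± 0.75), AT3G01230 (2.90 ± 1.67), AT1G51030 (2.81 ± 0.44), AT4G16880 (2.71 ± 0.25) and the ethylene biosynthesis gene AT1G12010 (2.69 ± 0.88) were next, of which AT1G51030 passed only narrowly, with a limma adjusted p of 0.047. AT1G51030 lost its call under 14 of the alternatives, among them without 72 h replicates 1 to 4 (adjusted p = 0.11, 0.069, 0.12 and 0.13) and without 12 h replicates 1 to 3 (0.066, 0.052 and 0.065). The falls were led by AT2G30540, at -4.07 ± 0.55 (16.8-fold), AT4G23670, of the major latex protein family, at -3.88 ± 0.63, and AT1G68230, at -3.58 ± 0.55. AT2G32870 (-3.50 ± 1.76), AOP3 (-3.48 ± 0.39) and AT5G41470 (-3.40 ± 1.62) followed, with adjusted p between 1.3e-06 for AT2G30540 and 0.00042 for AT5G41470. NAI1, measured on 3 arrays and named here after its value was seen, was at -3.69 ± 1.54 (adjusted p = 0.0058). AT1G12010 did not pass with quantile normalisation (adjusted p = 0.063), nor AT5G41470 with the 72 h arrays fitted alone (0.071).

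INO, YAB3, JAG, AMS and EMS1 were lower at 72 h. INO, a YABBY gene of the outer integument of the ovule, was at -0.84 ± 0.22 (n = 4; limma adjusted p = 0.00089), with YAB3 at -0.97 ± 0.37 (adjusted p = 0.00041) and JAG at -0.76 ± 0.60 (lower on 3 of 4 arrays; adjusted p = 0.011). AMS was at -0.67 ± 0.23 (adjusted p = 0.00047) and EMS1, a receptor kinase gene needed for the tapetum, at -0.63 ± 0.35 (adjusted p = 0.0065). RBE stayed higher, at 1.13 ± 0.25 (adjusted p = 0.00011), and ARR15 lower, at -1.10 ± 0.55 (adjusted p = 0.0017). The auxin biosynthesis gene YUC4 was at -0.57 ± 0.30 (adjusted p = 0.0046) and PORB, of chlorophyll synthesis, at -0.67 ± 0.21 (adjusted p = 0.0047). With the 72 h arrays fitted alone INO (adjusted p = 0.064), JAG (0.11), AMS (0.082), EMS1 (0.18), ARR15 (0.073), YUC4 (0.12) and PORB (0.11) did not pass. JAG also did not pass without 72 h replicates 1 or 4 (0.054 and 0.057). With limit values kept EMS1 did not pass (0.79), and with array weights PORB did not (0.052).

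The number of changed features at 72 h was 3758, 1791 higher and 1967 lower. The fit shared one estimate of the spread between time points, and the 72 h arrays spread most. Fitted alone, the 72 h arrays gave 614, and without 72 h replicate 4 the count was 2389. It was 2005 at adjusted p under 0.01 and 2403 with a limit of 1.5-fold added. Without 72 h replicate 2 the balance turned, with 2006 higher and 1791 lower. The median absolute log2 ratio was 0.50 on 72 h replicate 3 and 0.20 to 0.28 on the other 11 arrays.

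**Figure D1:**
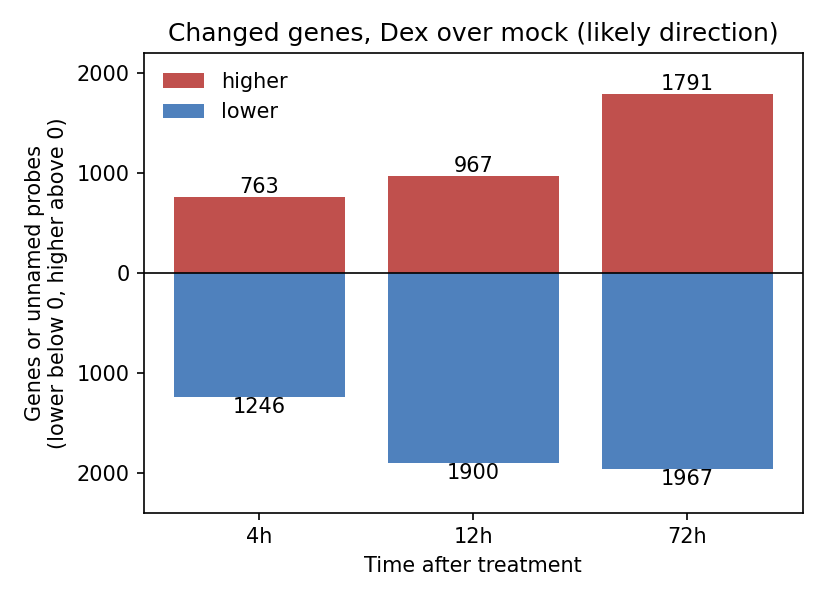
Features higher (above 0) and lower (below 0) at 4, 12 and 72 h after treatment, at limma adjusted p under 0.05 in the fit of all 12 arrays. Lower features outnumbered higher ones at each time point, by 1900 to 967 at 12 h, but without 72 h replicate 2 the balance at 72 h turned to 2006 higher and 1791 lower.

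**Figure D2:**
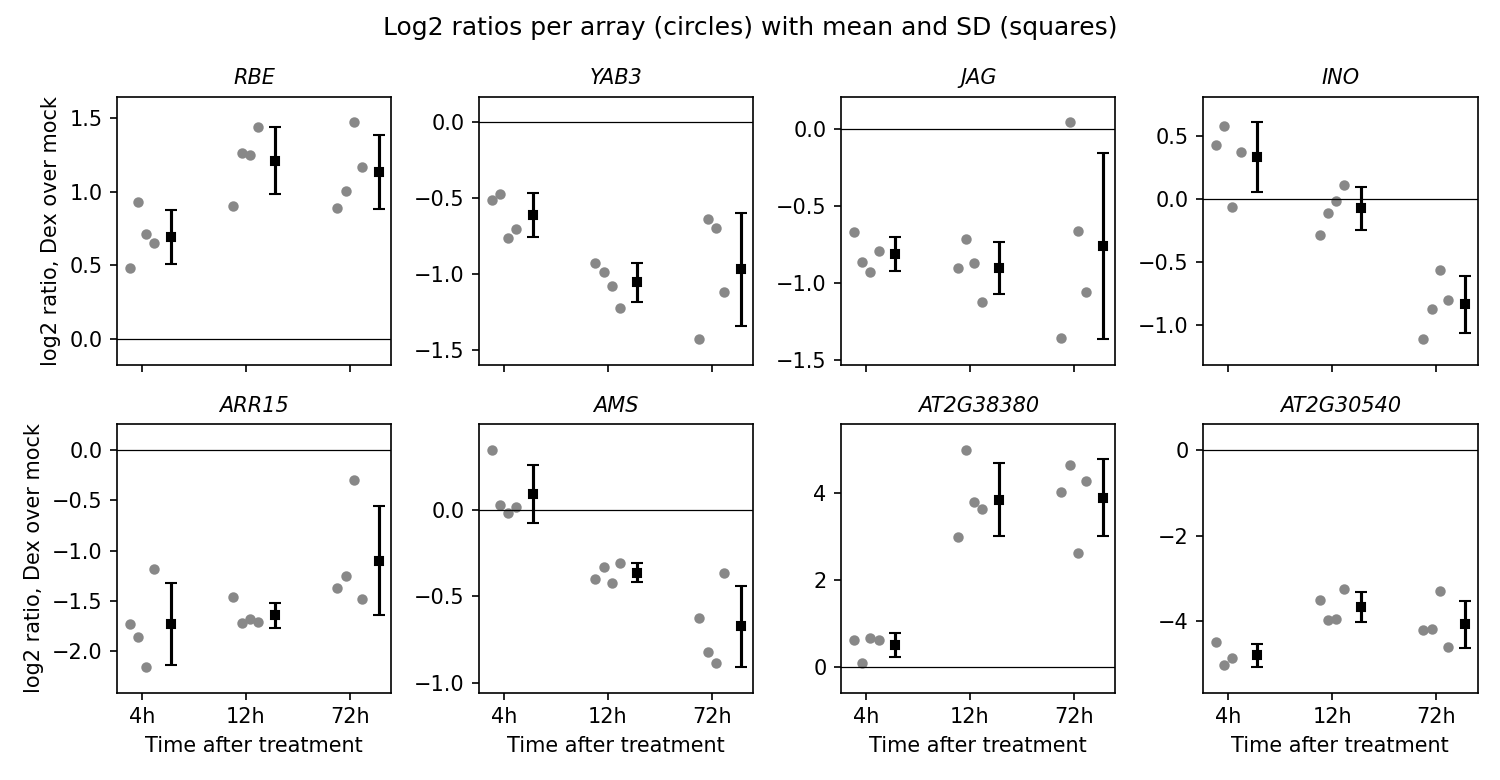
Centred log2 ratios of 8 genes on each array (circles) with the mean and SD over the arrays of a time point (squares), against time after treatment, each panel with its own vertical scale. RBE lay above 0 on all arrays, ARR15 and YAB3 below 0 on all arrays, and AT2G30540 lay below -3 throughout.

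Of the 276 loci in the fixed lists, 30 had a named probe used here and 27 were measured, so most lists are represented by few members. The organ polarity and outgrowth list had 4 measured members, of which YAB3 and JAG fell at 4 and 12 h, and YAB3, JAG and INO at 72 h. When adjusted over the list alone 3, 3 and 4 members passed. The added member at 4 h was INO, which lay on the higher side at 0.33 ± 0.28 (-0.07 ± 0.17 at 12 h), and the added member at 12 and 72 h was PHV, at -0.38 ± 0.18 and -0.36 ± 0.31. The list lay below other genes at 12 h and 72 h (cameraPR adjusted p = 0.033 and 0.0033), and not past the threshold at 4 h (adjusted p = 0.50). With an estimated correlation the adjusted p was 0.12 at 12 h and 0.057 at 72 h, so neither call held. The call at 12 h was also lost without 12 h replicate 1 (adjusted p = 0.064) or 72 h replicate 3 (0.080), with quantile normalisation (0.076) and with no minimum number of arrays (0.077).

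The shoot meristem and organ boundary list had 5 measured members. RBE rose at each of the 3 time points and PTL fell at 4 h, while CLV3, LOB and LAS did not pass the test at any time point (3, 1 and 1 members passed when adjusted over the list alone, LOB at -1.07 ± 1.38 being the added one at 4 h), and the list test gave adjusted p = 0.95, 0.70 and 0.34. The list's test pointed up at 12 and 72 h, whereas its median log2 ratio was -0.26 and -0.01. Of the 3 measured anther, tapetum and pollen wall genes, 0 changed at 4 h, AMS fell at 12 h, and AMS and EMS1 fell at 72 h (0, 1 and 2 adjusted over the list alone), with SPL at -0.10 ± 0.04 at 72 h. That list's adjusted p was 0.50, 0.77 and 0.032, and the last did not hold under several alternatives, with adjusted p = 0.13 with the 72 h arrays fitted alone, 0.13, 0.16 and 0.15 without 4 h replicates 1, 3 and 4, and 0.10 and 0.072 without 72 h replicates 1 and 3. It was 0.13 with genes on all 12 arrays, 0.14 with array weights, 0.061 with the dye from the blank spots and 0.15 with limit values kept. A list test with an estimated correlation could not be run for it, having fewer than 3 members with all 12 values.

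Of the 2 measured type-A response regulators, ARR15 fell at each time point and ARR16 lay at -0.20 ± 0.39, -0.19 ± 0.28 and -0.21 ± 0.57 (1 past the test adjusted over the list alone at each time). Of the 3 early auxin response genes, IAA29 fell at 4 h and lay at 0.33 ± 0.92 at 12 h, and IAA30 and GH3.3 did not pass (1, 0 and 0 adjusted over the list alone); the list test gave adjusted p = 0.50, 0.79 and 0.73. YUC2 did not pass at any time and YUC4 passed at 72 h, and at all 3 time points YUC4 alone, 1 of the 2 auxin synthesis genes, passed when adjusted over the list alone. Of the jasmonate genes, JMT fell at 4 and 12 h and PDF1.2 did not pass. Adjusted over the list alone 1 passed at each time point, JMT at 4 and 12 h and PDF1.2, at -0.83 ± 1.03, at 72 h. Among photosynthesis genes, LHCB4.1 fell at 12 h and PORB at 72 h (0, 2 and 1 adjusted over the list alone, PORB at -0.34 ± 0.37 being the added one at 12 h).

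Single members stood for the remaining lists and did not pass the test over all genes. UFO, for floral meristem and organ identity, lay at 0.06 ± 0.31, -0.10 ± 0.11 and 0.13 ± 0.14 at 4, 12 and 72 h, and AUR1, for the mitotic cell cycle, at -0.08 ± 0.21, 0.10 ± 0.20 and -0.07 ± 0.20. KIN1, for abscisic acid and dehydration, lay at 0.64 ± 0.96, 0.51 ± 0.98 and 0.91 ± 0.92, and GI, for the circadian clock, at -0.23 ± 0.37, 0.04 ± 0.28 and -0.34 ± 0.03. KIN1 and GI passed at 72 h when adjusted over the list alone, each being the only measured gene of its list. The lists of GATA factors, cytokinin synthesis and breakdown, gibberellin, brassinosteroid, touch, heat and pathogen response, epidermis, and vascular tissue had 0 measured members.

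Between 4 h and 12 h, among named genes past the threshold, the peroxidase gene AT2G38380 and BGLU47 gained most. AT2G38380 went from 0.49 ± 0.27 to 3.85 ± 0.83, a difference of 3.36 (SE 0.45; limma adjusted p = 0.0063), and BGLU47 from 0.26 ± 0.27 (n = 3) to 3.33 ± 0.49 (difference 3.07; SE 0.24; adjusted p = 0.00097). AT1G36640, lower at 4 h (-1.77 ± 0.16), was higher at 12 h (difference 2.96; SE 0.37; adjusted p = 0.0063), AT5G14730 went from -1.39 ± 1.08 to 1.39 ± 0.37 and AT1G26410 from -2.39 ± 0.29 to 0.20 ± 0.08. The carboxypeptidase-like gene scpl31 dropped from 0.23 ± 0.30 to -1.75 ± 0.23 (difference -1.98; SE 0.14; adjusted p = 0.00023), AT4G23670 from -0.79 ± 0.27 to -2.62 ± 0.41 and AOP3 from -1.35 ± 0.30 to -3.17 ± 0.39, followed by AT2G26390 (difference -1.80) and AT5G59990 (difference -1.70). The difference of AT5G14730 did not pass without 4 h replicates 1 or 4 (adjusted p = 0.065 and 0.080) or 12 h replicates 1 to 4 (0.050, 0.095, 0.10 and 0.094). That of AT4G23670 did not pass without 12 h replicate 3 (0.066), with equal median absolute deviations (0.061) or with a replicate block (0.062). With limit values kept the difference of BGLU47 was 1.48 (adjusted p = 0.95), and those of AT1G36640 (0.55), AT2G26390 (0.87), AT5G14730 (0.079) and AT4G23670 (0.053) did not pass either.

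The response differed between 12 h and 4 h in 441 features, 188 with a higher and 253 with a lower log2 ratio at 12 h. This count moved widely, from 81 at adjusted p under 0.01 to 3095 with array weights. It was 157 with a replicate block, 138 with limit values kept and 860 with only the 8 arrays compared. Equal median absolute deviations gave 782, quantile normalisation 720 and the dye from the blank spots 679. It was 229, 134, 100 and 107 without 12 h replicates 1 to 4, 139, 223 and 243 without 4 h replicates 2 to 4, and 961 without 72 h replicate 3.

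Opposite calls at 4 h and 72 h were made for 93 features. Of the genes named in this paragraph only AT5G39580 was among them. The peroxidase gene AT5G39580 was lower at 4 h (-1.41 ± 0.66) and higher at 72 h (2.12 ± 0.37, n = 4 each), a difference of 3.53 (SE 0.25; limma adjusted p = 8.5e-05). AT3G09950 went from -0.42 ± 0.30 to 3.09 ± 0.75 (SE of the difference 0.23; adjusted p = 6.2e-05), AT1G56380 from -2.49 ± 0.57 to 0.97 ± 2.19, AT2G38380 from 0.49 ± 0.27 to 3.90 ± 0.88 and AT3G01230 from -0.31 ± 0.42 to 2.90 ± 1.67. The positive mean of AT1G56380 at 72 h rested on 72 h replicate 3, at 4.18. Replicates 1, 2 and 4 lay at 0.59, -0.38 and -0.50. On the other side AT1G68230 went from -0.02 ± 0.44 to -3.58 ± 0.55 (difference -3.56; SE 0.29; adjusted p = 0.00018), AT2G32870 from 0.05 ± 0.53 to -3.50 ± 1.76, AT4G10290 from 1.18 ± 0.46 to -2.30 ± 1.77, AT5G41470 from -0.02 ± 0.29 to -3.40 ± 1.62 and NRT2.5 from 2.03 ± 0.51 to -1.19 ± 1.91 (n = 3). The differences of AT1G56380 (without 4 h replicates 2 to 4 or 72 h replicate 1; adjusted p = 0.064, 0.078, 0.060 and 0.055), AT4G10290 (without 4 h replicate 4; 0.051) and NRT2.5 (without 4 h replicates 1, 2 or 4; 0.052, 0.052 and 0.073) were lost on leaving out an array. With limit values kept the difference of NRT2.5 was -1.25 (adjusted p = 0.82), and that of AT1G56380 did not pass (0.076). With only the 8 arrays compared the differences of AT5G41470 (adjusted p = 0.054), AT4G10290 (0.067), NRT2.5 (0.071) and AT1G56380 (0.12) did not pass, nor did those of NRT2.5 (0.071) and AT1G56380 (0.073) with a replicate block. The responses at 72 h and 4 h differed in 1549 features, 902 with a higher and 647 with a lower ratio at 72 h, and the count was 1022 without 4 h replicate 4, 1006 without 72 h replicate 4 and 592 with only the 8 arrays compared. It was 3279 with array weights, 601 at adjusted p under 0.01, 1010 with a replicate block and 873 with limit values kept.

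From 12 h to 72 h the purine permease gene PUP18 changed sides, from -1.55 ± 0.35 to 1.88 ± 0.56 (n = 4 each; difference 3.43; SE 0.19; limma adjusted p = 5.0e-05). AT5G39110 went from -1.64 ± 0.21 to 1.27 ± 0.60 and AT3G01230 from -0.00 ± 0.29 to 2.90 ± 1.67. AT3G09950 gained 2.71 and AT3G56220 2.70. AT2G32870 went from -0.19 ± 0.63 to -3.50 ± 1.76 (difference -3.31; SE 0.61; adjusted p = 0.017), as did AT1G68230, from -0.48 ± 0.23 to -3.58 ± 0.55, while NRT2.5 lay at 1.85 ± 0.57 and then at -1.19 ± 1.91 (n = 3; adjusted p = 0.049). BGLU47 went from 3.33 ± 0.49 to 0.57 ± 0.17 and GSTF4 from -0.71 ± 0.12 to -3.31 ± 1.03. The difference of AT3G01230 did not pass without 12 h replicates 1, 2 or 4 (adjusted p = 0.063, 0.052 and 0.085). That of AT2G32870 did not pass without 12 h replicates 2 to 4 (0.062, 0.052 and 0.065) or 72 h replicate 4 (0.051). The difference of NRT2.5 did not pass without any 1 of the 4 h arrays (0.065, 0.074, 0.057 and 0.070) or 12 h arrays (0.054, 0.13, 0.12 and 0.14). With limit values kept the differences of BGLU47 (adjusted p = 0.38), NRT2.5 (0.90), AT3G01230 (0.082) and AT2G32870 (0.067) did not pass. With only the 8 arrays compared those of AT3G01230 (adjusted p = 0.073) and NRT2.5 (0.14) did not pass, nor with a replicate block those of AT2G32870 (0.062) and NRT2.5 (0.12). That of NRT2.5 was also lost with robust empirical Bayes (0.062) and with no minimum number of arrays (0.068). In all 750 features differed, 497 with a higher and 253 with a lower ratio at 72 h. The count was 437, 257, 294 and 212 without 12 h replicates 1 to 4, 300 without 72 h replicate 4 and 327 with only the 8 arrays compared. It was 2807 with array weights, 167 at adjusted p under 0.01, 327 with a replicate block and 236 with limit values kept.

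The time points shared much of their response. Of the features lower at 4 h, 880 (70.6%) were also lower at 12 h, where independent lists would share 131, and 634 (50.9%) were lower at 72 h, where independent lists would share 135. Of those higher at 4 h, 329 (43.1%) were also higher at 12 h and 321 (42.1%) at 72 h, against 40.7 and 75.4 for independent lists. Between 12 h and 72 h, 1065 lower and 487 higher features were shared, against 206 and 95.6. Fisher's exact test, two-sided, gave p of at most 3.7e-128 in each of these 6 tests, with odds ratios from 7.85 to 37.4. The test treats features as independent, which they are not, so these p-values overstate the certainty. With each time point fitted on its own arrays the shared numbers at 4 and 72 h were 35 higher and 165 lower, against 4.72 and 16.1 for independent lists. Leaving out 1 array moved only shared rises by over 1.5 times. Those at 4 and 12 h moved to 201 and 214 without 4 h replicates 2 and 4 and to 210, 201 and 203 without 12 h replicates 2 to 4. Those at 4 and 72 h moved to 181 and 197 without 4 h replicates 2 and 4 and to 197 without 72 h replicate 4. Those at 12 and 72 h moved to 316, 301 and 316 without 12 h replicates 2 to 4. No mock RNA is shared between time points, although the fit shares its spread.

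In the same direction at all 3 time points were 807 features, 226 higher and 581 lower. Opposite calls were fewer, 19 between 4 and 12 h, 52 between 12 and 72 h and 93 between 4 and 72 h. Across the 18125 features, which are not independent replicates, the mean log2 ratios correlated at 0.56 between 4 and 12 h, 0.52 between 12 and 72 h and 0.30 between 4 and 72 h (Pearson), or 0.45, 0.42 and 0.22 (Spearman).

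**Figure D3:**
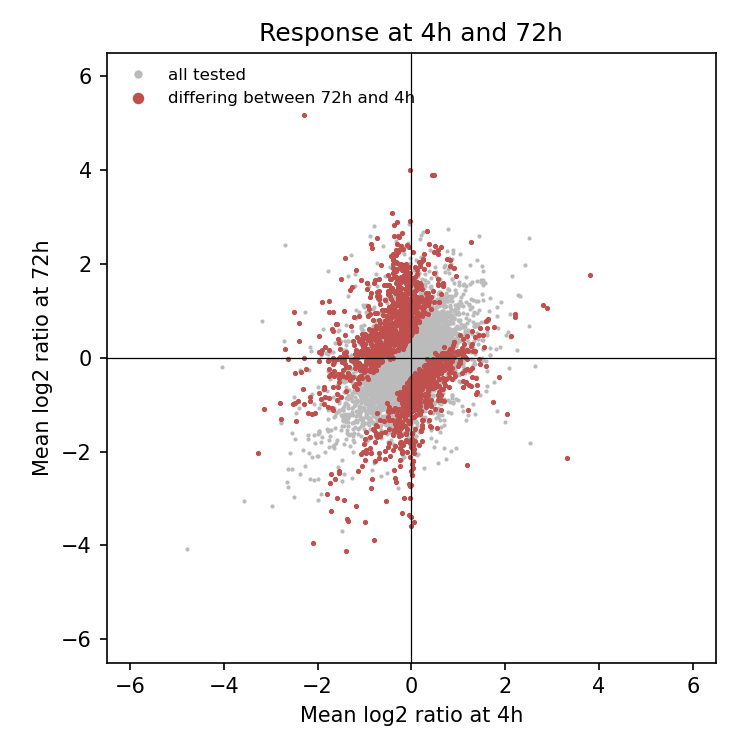
Mean log2 ratio at 4 h (horizontal axis) against that at 72 h (vertical axis) for the 18125 tested features, with the 1549 that differed between these times in red. The correlation across features was 0.30.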

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

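The tests of exchanged dyes, of inverted ratios and of another time point were chosen after the result was seen, and for the slope and the noise of 72 h replicate 3 the reading was changed after the value was seen, as said there.

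The response differed by a test of the difference itself in 441 features between 12 and 4 h, in 1549 between 72 and 4 h and in 750 between 72 and 12 h. Among 35 splits of the 8 arrays compared, 1 (the real one) gave as many in each case, and the highest of the other splits gave 2, 9 and 0 by limma. A share of 1 in 35 is the smallest these splits can give, and it was not adjusted over the comparisons. The other splits mix arrays of both time points. They show that the arrays group by time point and do not test the counts themselves. For the changes at single time points only 8 assignments of sign exist, too few for a share under 0.05; 1 of the 8, the real one, gave 2009, 2867 and 3758 features, and the highest other gave 40, 3 and 132. Among named genes past the threshold, the largest differences between 12 and 4 h were 3.36 in AT2G38380 and -1.98 in scpl31, on the log2 scale. Those between 72 and 4 h were 3.53 in AT5G39580 and -3.56 in AT1G68230, and those between 72 and 12 h 3.43 in PUP18 and -3.31 in AT2G32870.

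Of 74 groups of 4 arrays examined, 6 had an array far from the other 3, and chance gives about 1 in 20. The number of gene probes without a value was 3761 on 4 h replicate 4, 4202 on 12 h replicate 4 and 4185 on 72 h replicate 4, each the highest of its time point. AT1G61660 was at -2.21 and AT1G33760 at 1.77 on 4 h replicate 3, and AOP3 at -2.90 on 72 h replicate 1, each nearest to 0 among its 4 arrays.

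The blank spots, which enter no comparison, had medians at a limit, and the median was -6.64 on 4 h replicate 1 and 6.64 on 4 h replicate 3. On the other 10 arrays the sign was positive where Dex is labelled Cy5 and negative where it is labelled Cy3, and on these 2 it was the opposite. Ratios deposited the other way up on these 2 arrays are argued against, since below the limits they correlated with replicates 2 and 4 at 0.18 or more. Exchanged dyes in the labels are a candidate explanation, since the dye effect of the 12 and 72 h arrays correlated with the deviation of each 4 h array in the sense of its blank spots, at 0.31 or more. This is a hypothesis found on the same data, no biological explanation was tested, and the means per time point hold both dyes equally either way. The counts do depend on the dye used. The dye term passed for 0 features with the labelled dye and for 815 with the dye from the blank spots. With the latter 2346, 3306 and 4419 features changed at 4, 12 and 72 h. Between 12 and 4 h, 72 and 4 h and 72 and 12 h, 679, 1911 and 1037 then differed.

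On 72 h replicate 3 the ratios spread most, with a median absolute log2 ratio of 0.50. RNA of another time point on this array is argued against, since its correlation with the mean of the other 72 h arrays (0.42) exceeded that with the 12 h mean by 0.13. A smaller response would not by itself account for the wider spread. Whether this array also responded less stays open: over 3294 features its slope on the other 72 h arrays was 0.80 (SE 0.01). The other 3 had slopes of 0.75 to 1.04 over the same features. These features were chosen by calls at 72 h that used those 3 arrays but not replicate 3. That choice can raise their slopes, so the range is not a like yardstick. The SE treats features as independent, which they are not. A slope above 0.8 had been set beforehand as evidence against a smaller response, and the requirement that it be exceeded by 2 SE was added after the value was seen; the excess is below 1 SE. More noise stays open too: its test compared probes of one gene, but only 1 of 179 such genes had probes with different values, AT5G22700, whose probes have different gene IDs. The ratio first obtained, which pointed to more noise, rested on that gene and was set aside. No biological explanation was tested.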

How the results depend on the processing

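The alternatives added after seeing the data were the dye from the blank spots, limit values kept and identical rows kept once, and so were the checks of the replicate numbers with other dye effects taken out. The alternatives changed no direction of a named gene: of 125 pairs of a named gene and a time or difference, 0 reversed, 84 kept their side of the threshold and 41 lost their call in at least 1 setting. The causes of the moves below were not tested. Signal over background is unknown for ratios, so no depth limit can be given.

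With only the arrays compared in the fit, 1145, 4801 and 614 features changed at 4, 12 and 72 h and 860, 592 and 327 differed between 12 and 4 h, 72 and 4 h and 72 and 12 h. Shared features were then 219 higher at 4 and 12 h, 35 higher and 165 lower at 4 and 72 h, and 122 higher and 294 lower at 12 and 72 h. With array weights 4619 and 6851 changed at 4 and 12 h, 3095, 3279 and 2807 differed, and 973 higher and 1639 lower, 692 and 1129, and 1058 and 1687 were shared by 4 and 12 h, 4 and 72 h, and 12 and 72 h. At adjusted p under 0.01, 1200, 1671 and 2005 changed, 81, 601 and 167 differed, and 154 and 564, 139 and 389, and 223 and 642 were shared. At adjusted p under 0.05 and at least 1.5-fold, 1854 and 2403 changed at 12 and 72 h, and 187, 172 and 274 higher (and 699 lower at 12 and 72 h) were shared.

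Between 12 and 4 h, 782 features differed with equal median absolute deviations, 720 with quantile normalisation and 679 with the dye from the blank spots. With limit values kept 138, 873 and 236 differed. With a replicate block 157, 1010 and 327 differed, and 1664, 2396 and 3073 changed at single times. The numbers were not taken to pair the arrays. With the pooled dye effect taken out, 6 of 12 pairs with the same number correlated over 0.1 (range -0.19 to 0.32), among them all 4 pairs of 4 and 72 h, and 5 of 12 arrays correlated best with one of their own number. With no dye effect taken out those 4 pairs lay at -0.22 to -0.09 and the 4 pairs of 4 and 12 h at 0.18 to 0.32. Blank spots had opposite signs in all of the former and equal signs in all of the latter. With each time point's own dye effect taken out, the 12 pairs lay between -0.06 and 0.07.

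Leaving out each array in turn gave 1315 (without 4 h replicate 2) to 2703, 1753 (12 h replicate 4) to 3812 and 2389 (72 h replicate 4) to 3797 changed features at 4, 12 and 72 h, and 100 (12 h replicate 3) to 961 (72 h replicate 3), 1006 (72 h replicate 4) to 1666 and 212 (12 h replicate 4) to 793 differing. Shared higher features ranged from 201 to 455, 181 to 380 and 301 to 566.

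For the organ polarity list the adjusted p at 12 h was 0.076 with quantile normalisation, 0.077 with no minimum number of arrays, 0.12 with an estimated correlation and 0.0099 to 0.080 leaving out arrays, and at 72 h 0.057 with an estimated correlation. For the anther list at 72 h it was 0.13 with only the arrays compared, 0.13 with genes on all 12 arrays, 0.14 with array weights, 0.061 with the dye from the blank spots, 0.15 with limit values kept and 0.014 to 0.16 leaving out arrays. By fry, which tests whether a list's own genes move one way on average and does not compare them with other genes, organ polarity passed downward at 4, 12 and 72 h (adjusted p = 0.022, 0.00036 and 5.3e-05). Early auxin passed downward at 4 h (0.040), and organ boundary upward at 12 h (0.033) and 72 h (0.0012). The members did not all move that way. At 12 h RBE lay at 1.21, but LOB, PTL and LAS at -0.31, -0.26 and -0.10. At 72 h RBE and LOB lay at 1.13 and 0.69, but PTL and LAS at -0.01 and -0.27. At 4 h IAA29 and GH3.3 lay at -1.51 and -0.52, but IAA30 at 0.24. The families' adjusted p of 0.036 rose to 0.87 with an estimated correlation.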

Other observations

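The test of symbol families and the glutaredoxin list were chosen after the data were seen, and of the glutaredoxins only members whose values had not been seen enter the tests of explanations.

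At 12 h the SWEET, UGT and CYP families lay below other genes with a preset correlation (cameraPR adjusted p = 0.036 for each, over the 24 families tested), and did not pass with an estimated correlation (adjusted p = 0.87 for each). Of 12 measured SWEET sugar transporter genes, 4 fell and 0 rose, led by SWEET11 (-1.79), SWEET1 (-1.60) and SWEET10 (-1.16). Of 38 UGT glycosyltransferase genes, 10 fell, UGT88A1 (-1.58) and UGT74B1 (-1.38) most, and 2 rose, UGT73C6 (1.14) among them. Of 18 CYP genes, 5 fell and 1 rose: CYP71B23 was at -2.29, CYP71B22 at -2.06 and CYP71B24 at 1.69. The CYP set was formed by symbol and holds mostly CYP71B genes, as are all its members called at 12 h. It does not stand for all cytochrome P450 genes, and cross-hybridisation among its members was not tested. Over the other alternatives the adjusted p ranged from 0.010 to 0.12 for SWEET, 0.0093 to 0.16 for UGT and 0.0029 to 0.14 for CYP. Among arrays left out, 12 h replicates 2 and 3 and 72 h replicate 3 ended all of these calls (SWEET 0.12, 0.050 and 0.091; UGT 0.14, 0.050 and 0.15; CYP 0.14, 0.050 and 0.091). Leaving out 12 h replicate 1 ended that of SWEET (0.091), and 72 h replicates 2 and 4 that of UGT (0.063 and 0.074). At 4 and 72 h no family passed, the lowest adjusted p being 0.062, for SWEET at 72 h.

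CC-type glutaredoxins are small redox proteins, of which ROXY1 and ROXY2 act in petal and anther development. The list was written after falls of 5 members had been seen, so it does not show that the family is frequent among falls. Of 16 measured members of 21, 8 were lower at 4 h, 10 at 12 h and 7 at 72 h, and 0, 1 and 2 were higher. These counts include those 5, and of the other 11, 3, 5 and 2 were lower. AT1G06830, among the 11, lay at -3.19 ± 0.15 at 4 h and -2.76 ± 0.30 at 12 h without passing (limma adjusted p = 0.064 and 0.088). At 72 h it lay at 0.78 ± 3.61. With values as deposited, equal median absolute deviations or quantile normalisation 8 to 9, 10 to 11 and 6 to 7 of the 16 were lower. ROXY1 was at -0.55 ± 0.24 and ROXY2 at -1.07 ± 0.32 at 12 h (SD, n = 4; limma adjusted p = 0.0081 and 0.0065), and neither passed at 4 or 72 h, though their responses at 12 h did not differ from those at 4 h past the threshold (adjusted p = 0.057 and 0.52). The list was written before the values of ROXY1 and ROXY2 were looked at, and they are named here after.

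A fall of the whole family is one hypothesis, tested on the 11 members that had not been seen. Their median was -0.11 at 4 h, -0.55 at 12 h and 0.01 at 72 h (-0.06 to -0.02 at 72 h under the other scalings). CameraPR gave an adjusted p, over the 3 time points, of 0.13 at 4 h, 0.13 at 12 h and 0.66 at 72 h, so a family-wide fall stays open. AT5G11930 (1.32 ± 0.41) and AT4G33040 (1.01 ± 0.38) went the other way at 72 h, and AT5G11930 also at 12 h (0.49 ± 0.25, limma adjusted p = 0.047). Cross-hybridisation among the tandem copies on chromosome 4 could join the values of AT4G15660, AT4G15670, AT4G15680 and AT4G15700. The 10 unseen members outside this group had a median of -0.39 at 12 h, between the bounds set beforehand, so it cannot be told apart from a family-wide fall, because the members went both ways. AT2G30540 and AT3G62930, at -3.67 and -3.12 at 12 h, lie outside the group. AT3G62930 is itself grouped with AT3G62950 and AT3G62960 on chromosome 3, at -1.31 and -1.08 at 12 h, and cross-hybridisation there was not tested. Inside the chromosome 4 group AT4G15700 lay at -1.34 ± 0.18 at 12 h. AT4G15660, AT4G15670 and AT4G15680 (n = 3) lay at -2.44, -2.50 and -2.66.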
